A study of Triticum aestivum with 25 samples.

How the data were processed

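RNA was taken from flag leaves of wheat cultivar Thatcher in 25 samples, 5 in each of 5 groups: mock at 0, 7 and 14 d, and infected with leaf rust at 7 and 14 d. Groups and days come from the sample labels. Per the labels' protocols, infected samples were extracted with a Zymo Direct-zol kit and made into libraries with a TruSeq Stranded mRNA kit. Mock samples were extracted with a Monarch kit and made into libraries with an Illumina Stranded mRNA Ligation kit. Both library kits select polyadenylated RNA and mark the strand.

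The deposited values, one per transcript and library, are on a log2-like scale and cover 83595 transcripts of 65144 genes. Per the submitters' processing notes, fastp, Salmon and DESeq2 were used, with no version, role or order. The reference transcriptome is not given in the sources used here. Every library shares a floor of 7.673, and the deposited values have the form of the authors' named DESeq2 tool's variance-stabilizing transformation, with the floor at an estimated count of 0. The closed form of that transformation was inverted from the floor to give normalized counts. This form was inferred from the deposited log2 values and is not stated in the labels. A normalized count of 10 corresponds to 7.992 and one of 100 to 8.664, and a step of 1 unit from a count of 0 takes 102 normalized counts, so differences of low transcripts are understated on the deposited scale. Estimated counts divide reads among similar transcripts, so values of transcripts of 1 gene and of near-identical gene copies in the A, B and D subgenomes are uncertain.

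Depth was estimated from the spacing of the low back-transformed values of each library, taken as 1 read, and from the sum of normalized counts. It covers reads assigned to the wheat transcripts in the table and leaves out all others. Of the low values, 58.6% to 90.2% lay within 0.25 read of a whole number from 1 to 3. The spacing was placed where these same values were densest, so they crowd near 1 read by construction. The share therefore has no chance level to be set against and does not show that the spacing is right. The share was 62.6 ± 1.81% at infected 7 d and 59.98 ± 1.19% at infected 14 d (mean ± SD, n = 5). It was 75.72 ± 8.17% at mock 0 d, 72.6 ± 7.38% at mock 7 d and 77.16 ± 6.76% at mock 14 d. The spacing, and with it depth and the ranking of libraries by depth, is therefore less certain in infected libraries. Depth was 27.6 ± 4.58 M reads (M, mega) at mock 0 d, 31.2 ± 2.35 at mock 7 d, 28.4 ± 2.32 at mock 14 d, 16.8 ± 4.1 at infected 7 d and 21.4 ± 4.63 at infected 14 d (mean ± SD, n = 5). Whole reads were not recovered, so no count model was fitted. A fold against a group at 0 was computed against 3 reads over the group and covers counting error only. Such a fold rests on the same spacing. Replicates of 1 group were compared with counting noise for transcripts with a mean of at least 50 normalized counts in the pair. Their median squared difference was 5.21 to 30.4 times that of counting noise. Of the pairs of replicates, 0 held identical values.

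Tests used limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8). The deposited values of the 57301 transcripts with a mean of at least 10 normalized counts entered a one-way model of the 5 groups with a mean-variance trend, with no covariate. A call needed a Benjamini-Hochberg adjusted p under 0.05 within the comparison and a difference of at least 1 unit. The 7 comparisons were mock 7 d against 0 d, mock 14 d against 0 d, mock 14 d against 7 d, infected 14 d against 7 d, infected against mock at 7 d and at 14 d, and the difference of the 7 to 14 d changes. The design fixed before the data were examined assumed a linear unit and a log2 scale with a pseudocount of 1. The deposited values were already on a log2 scale, so they were tested as they stand, and the pseudocount was moved to an alternative on back-transformed values. That alternative shifted the median of all tested transcripts by -0.174 in infected against mock leaves at 7 d and by -0.216 at 14 d.

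The named transcripts in each comparison are the called ones with the largest difference in each direction, 2 rising and 2 falling. They needed a mean of at least 100 normalized counts in the higher group and no overlap between the libraries of both groups, the last condition being dropped for the difference of changes. The design allowed 8 in each direction where genes can be named. The gene list used here, NCBI's for the assembly IWGSC CS RefSeq version 2.1, names genes by other identifiers than the deposited values do. No identifier of the 65144 genes could be looked up in it (0 matches), which says nothing of whether the assembly holds these genes, so no coordinates or names are given. For the same reason the 43 gene lists fixed before the data were examined were not tested. No identifier outside the wheat naming scheme was present (0 of all), so the share of pathogen reads and a rescaling to host genes were not analysed here.

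Medians of transcript sets and numbers of detected transcripts were compared with two-sided exact permutation tests. Alternatives covered the scaling of libraries, the filter on low values, the pseudocount, the variance trend, the libraries in the fit, the size of difference required, the replicate number as a block, and leaving out each replicate. Transcripts summed per gene and genes with 1 transcript only were added after seeing the data. So were the libraries without the 4 infected ones under 16 M reads. The deposited scale of the main test was also chosen then. Back-transformed values with a pseudocount of 1 are nearest to the scale fixed in advance, though the back-transformation itself was decided after seeing the data. The test was checked on simulated data with 50 transcripts at each of 4 fold changes, all with a mean of at least 50 normalized counts. It recovered 24 of 50 transcripts changed 4-fold and 35 of 50 changed 8-fold for mock 7 d against 0 d, and none of 50 changed 2-fold (0), with 1 false call among 57063 transcripts. For infected 14 d against 7 d it recovered 24 of 50 at 4-fold, 36 at 8-fold and 1 at 2-fold, with 2 false calls among 56964. A 2-fold change lies under 1 unit on the deposited scale, so its low recovery follows from the call rule. Each transcript was given the same spread in all groups. The few false calls therefore do not cover groups that differ in spread, and recovery of lower transcripts was not simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.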

Results

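Transcript abundance was measured by RNA sequencing in flag leaves of the bread wheat (Triticum aestivum) cultivar Thatcher. The flag leaf is the uppermost leaf of the wheat shoot. Infected plants had received spores of Puccinia triticina isolate TBDG, the fungus that produces wheat leaf rust, when flowering began. The series asks how infection alters gene expression over time. The 25 libraries fell into 5 groups of 5 libraries, namely mock leaves at 0, 7 and 14 d and infected leaves at 7 and 14 d. Infected and mock samples went through different RNA extraction kits and different library kits, so infection and kit cannot be told apart when the treatments are compared on the same day. Comparisons within mock leaves and within infected leaves each use 1 extraction kit and 1 library kit. Estimated depth was 24.3 to 35.2 M reads (M, mega) in mock libraries and 12.8 to 25.1 M reads in infected libraries. This depth counts reads assigned to wheat transcripts, and is less certain in infected libraries, whose low values lay less often near whole reads on average. Reads not assigned to these transcripts are left out, so it is not the number of reads sequenced. Whether any fungal reads were assigned to wheat transcripts was not examined. The labels do not say that replicates came from separate plants, so each p-value measures the spread between these samples. In limma this spread was pooled over all 5 groups for each transcript, so it is not that of the compared groups alone. The table pairs its identifiers with no gene name or function, so transcripts are given by identifier, with the chromosome that is part of it.

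Libraries separated by treatment and by day on the first 2 principal components, which held 27.9% and 22.4% of the variance. Correlations between replicates were 0.927 to 0.984 within the mock groups and 0.882 to 0.937 within the infected groups. Fewer transcripts had an estimated count above 0 in infected leaves. At 7 d these were 57170 ± 2790 in infected and 68940 ± 235 in mock leaves (mean ± SD, n = 5; two-sided exact permutation test, p = 0.00794, the smallest that 252 splits allow; adjusted p = 0.0106 over 4 comparisons). At 14 d they were 55890 ± 2440 and 67920 ± 346 with the same exact p and adjusted p. In mock leaves the number was lower at 14 d than at 7 d, also with exact p = 0.00794. No difference between the infected groups of 7 and 14 d passed this test (exact permutation p = 0.413). Mock 0 d replicate 5, at 24.3 M reads, had 14246 transcripts at 0. The infected 14 d libraries nearest to it in estimated depth, replicates 5, 1 and 2 at 25.1, 23.3 and 22.7 M reads, had 30147, 25393 and 25289. Infected 14 d replicate 3, at 13.3 M reads, had 30283, close to replicate 5. Estimated depth and detection thus did not go together for these libraries, as far as the estimated depth holds. At infected 7 d the deeper libraries had fewer at 0. Replicates 5 and 3, at 22.4 and 19.9 M reads, had 24080 and 24344. Replicates 1, 4 and 2, at 14.8, 14.3 and 12.8 M reads, had 31044, 26179 and 26465.

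**Figure D1:**
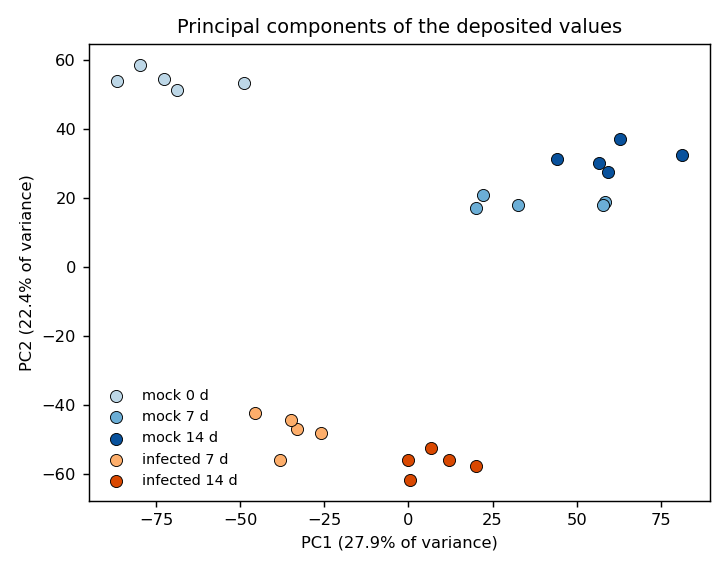
First and second principal components of the deposited log2-scale values, 1 point per library and 1 colour per group. Infected libraries lie apart from mock libraries on the second component, and mock libraries of 0 d lie apart from those of 7 and 14 d on the first, which holds 27.9% of the variance.

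In mock leaves, 1540 transcripts rose and 1926 fell from 0 to 7 d, out of 57301 tested. Among transcripts with a mean of at least 100 normalized counts in the higher group and no overlap between the groups, the largest rises were those of TraesCS3A03G0131600.1 on chromosome 3A and TraesCS3D03G0118800.1 on chromosome 3D. TraesCS3A03G0131600.1 went from 170.8 ± 358 to 24150 ± 2040 normalized counts (mean ± SD, n = 5), and TraesCS3D03G0118800.1 from 221 ± 403 to 24290 ± 3050. Their large spread at 0 d came from replicate 5, which held 811.3 and 939.3 normalized counts of these transcripts and without which the means were 10.7 and 41.4. TraesCS4D03G0245600.1 on chromosome 4D fell from 36960 ± 15800 to 96.7 ± 117 normalized counts, and TraesCS7D03G0117000.1 on chromosome 7D from 25050 ± 8510 to 47.2 ± 48.3. Without mock 7 d replicate 2 their means at 7 d were 44.7 and 25.7. On the deposited log2 scale the differences were 6.15 (SE 0.296) for TraesCS3A03G0131600.1 and 5.89 (SE 0.299) for TraesCS3D03G0118800.1. They were -6.54 (SE 0.39) for TraesCS4D03G0245600.1 and -6.26 (SE 0.345) for TraesCS7D03G0117000.1. In limma with Benjamini-Hochberg adjustment the adjusted p of these 4 transcripts was at most 1.5e-11. Without the minimum difference of 1 unit, 10289 transcripts rose and 11387 fell by the adjusted p. With the values transformed back to normalized counts and a log2 fold change of at least 1, 5557 rose and 6961 fell.

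The same 4 transcripts led the comparison of mock leaves at 14 and 0 d, which shares its 0 d libraries with the preceding one. Here 2600 transcripts rose and 1570 fell by at least 1 unit. TraesCS3A03G0131600.1 reached 39890 ± 4140 normalized counts at 14 d (mean ± SD, n = 5) and TraesCS3D03G0118800.1 reached 33310 ± 5050. TraesCS4D03G0245600.1 stood at 141.9 ± 180 and TraesCS7D03G0117000.1 at 97 ± 121, or at 78.5 and 45.7 without mock 14 d replicate 1. The log2 differences were 6.86 (SE 0.296), 6.34 (SE 0.299), -6.49 (SE 0.39) and -6.07 (SE 0.345) in that order. The adjusted p from limma was at most 1.61e-11. The excess of rises did not hold without the minimum on the deposited scale: 12758 rose and 12633 fell on adjusted p alone, and 7458 and 7309 on back-transformed values.

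Between 7 and 14 d, 1115 transcripts rose and 160 fell in mock leaves by at least 1 unit. TraesCS5A03G0146100.1 on chromosome 5A rose from 334.1 ± 140 to 17460 ± 4690 normalized counts (mean ± SD, n = 5). TraesCS2B03G1209500.1 on chromosome 2B rose from 9.71 ± 6.13 to 6240 ± 1540. TraesCS6D03G0112400.1 on chromosome 6D fell from 1747 ± 1170 to 82.3 ± 91.9, and TraesCS5B03G1001000.1 on chromosome 5B from 4505 ± 1290 to 782.1 ± 815. Their means at 14 d were 47.5 without replicate 4 and 442.6 without replicate 5, respectively. The log2 difference was 4.70 for both rising transcripts (SE 0.171 and 0.164). It was -2.46 (SE 0.328) for TraesCS6D03G0112400.1 and -2.34 (SE 0.378) for TraesCS5B03G1001000.1. The adjusted p from limma was 1.06e-14 and 5.98e-15 for the rises and 1.07e-05 and 0.000101 for the falls. The split was more even on adjusted p alone, with 6485 higher and 4225 lower, and on back-transformed values, with 3566 and 1796.

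In infected leaves, 522 transcripts rose and 882 fell from 7 to 14 d. TraesCS2D03G0011600.1 on chromosome 2D rose from 147 ± 51.2 to 6730 ± 3390 normalized counts (mean ± SD, n = 5), and TraesCS1B03G1132200.1 on chromosome 1B from 320.6 ± 83.3 to 6084 ± 3070. Both were also called as rising in mock leaves from 0 to 7 d, TraesCS2D03G0011600.1 from 39.6 ± 58.6 to 5840 ± 1890 (limma adjusted p = 7.8e-10) and TraesCS1B03G1132200.1 from 129.1 ± 111 to 11990 ± 5940 (limma adjusted p = 5.2e-09). TraesCS3A03G1037900.1 on chromosome 3A fell from 15550 ± 1790 to 662.8 ± 484. TraesCS7D03G0117000.1, among the transcripts with the largest falls in mock leaves from 0 to 7 d, fell in infected leaves from 6166 ± 3150 at 7 d to 280.2 ± 325 at 14 d. Its mean at 14 d was 145.6 without infected 14 d replicate 3, and that of TraesCS2D03G0011600.1 in mock leaves at 0 d was 13.4 without replicate 5. The log2 differences were 3.82 (SE 0.335), 3.13 (SE 0.418), -4.08 (SE 0.251) and -3.49 (SE 0.345), with adjusted p from limma between 2e-10 and 7.56e-06. On adjusted p alone 8120 transcripts rose and 8042 fell, on back-transformed values 3936 and 5584, and 899 were called when genes with 1 transcript in the table were tested alone. These tests pooled the spread over all 5 groups. With only the infected libraries in the fit, 10017 transcripts passed the adjusted p instead of 16162. By at least 1 unit, 424 then rose and 783 fell.

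**Figure D2:**
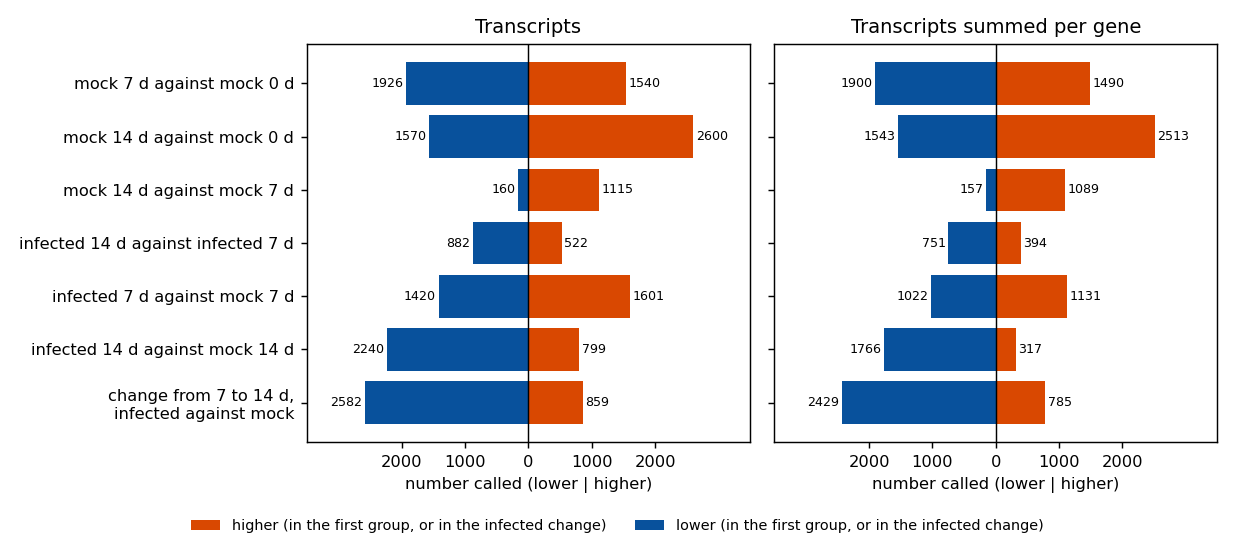
Number of transcripts (left) and of genes after summing their transcripts (right) called higher or lower in each comparison; bars start at 0 and carry their counts. In mock leaves from 7 to 14 d 1115 transcripts were higher and 160 lower, a split that was more even with no minimum difference (6485 and 4225).

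The transcripts that changed in mock leaves from 0 to 7 d were then followed through the infected libraries. These entered the choice of transcripts through the filter and the shared estimate of spread only, and 3419 of the 3466 transcripts were also called with the mock libraries compared alone in the fit. The median of the 1540 rising transcripts was 9.10 ± 0.19 at 0 d and 10.74 ± 0.23 at 7 d in mock leaves on the deposited log2 scale (mean ± SD, n = 5). In infected leaves it rose from 9.77 ± 0.099 at 7 d to 10.23 ± 0.13 at 14 d, a change of 0.468 (two-sided exact permutation test, p = 0.00794, adjusted p = 0.0159 over 4 sets). The median of the 1926 falling transcripts went from 10.51 ± 0.15 to 8.98 ± 0.09 in mock leaves from 0 to 7 d. It went from 9.58 ± 0.021 at 7 d to 9.06 ± 0.083 at 14 d in infected leaves, a change of -0.522 with the same exact p and adjusted p. Of the risen set, 74.7% of transcripts had a higher mean in infected leaves at 14 d than at 7 d, and of the fallen set 10.6%. Part of the calls were shared in the same direction: 266 transcripts rose both in mock leaves from 0 to 7 d and in infected leaves from 7 to 14 d, where 14 would be shared by independent lists, and 280 fell in both, against 29.6. Opposite calls numbered 27 and 6, against 23.7 and 17.5. These expected numbers are too low, since they take all tested transcripts as equally likely to be called. Of the calls, 3425 of 3466 in mock and 1399 of 1404 in infected leaves were also made among 39188 transcripts with a mean of at least 50 normalized counts. Across the 57301 transcripts, which are not independent replicates, the 2 sets of log2 differences had a Pearson correlation of 0.416 and a Spearman correlation of 0.369.

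The medians of the transcripts that changed in mock leaves from 7 to 14 d moved the other way in infected leaves over the same days, but their members went both ways. The median of the 1115 rising transcripts was 9.04 ± 0.16 at 7 d and 10.61 ± 0.29 at 14 d in mock leaves (mean ± SD, n = 5). In infected leaves it was 9.34 ± 0.096 at 7 d and 9.12 ± 0.074 at 14 d, a change of -0.216 (exact permutation p = 0.0159, adjusted p = 0.0212). The median of the 160 falling transcripts rose in infected leaves by 0.253 (exact permutation p = 0.0238, adjusted p = 0.0238). This last result was lost without infected 7 d replicate 1, 2 or 3, when the exact p reached up to 0.0556. Of the risen set, 40.4% of transcripts had a higher mean in infected leaves at 14 d than at 7 d, and of the fallen set 58.8%. Of the 1115 rising transcripts, 39 were also called as rising in infected leaves, where independent lists would share 10.2, and 93 as falling, against 17.2. Of the 160 falling ones, 11 were called as falling in infected leaves, against 2.46, and 24 as rising, against 1.46. These expected numbers are too low for the same reason as above. Calls exceeded them in both directions, so the excess by itself shows neither a shared nor an opposed change.

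**Figure D3:**
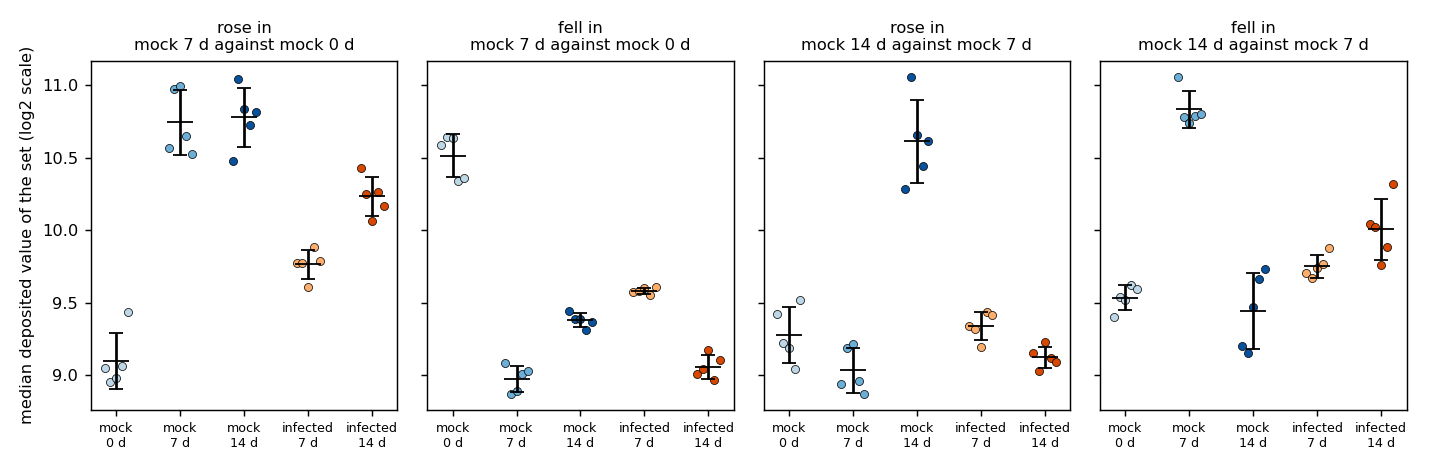
Median deposited value (log2 scale) of 4 sets of transcripts in each library, with group mean and SD (n = 5); the sets are those that rose or fell in mock leaves from 0 to 7 d and from 7 to 14 d. The set that rose in mock leaves from 7 to 14 d stood at 10.61 in mock and 9.12 in infected leaves at 14 d.

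At 7 d, 1601 transcripts were higher and 1420 lower in infected than in mock leaves, a comparison in which kits and infection changed together. TraesCS5D03G0413700.1 on chromosome 5D held 6175 ± 1160 normalized counts in infected and 1.42 ± 2.14 in mock leaves (mean ± SD, n = 5). TraesCS5B03G0441800.1 on chromosome 5B held 5782 ± 862 and 1.45 ± 1.32. TraesCS4A03G0202400.2 on chromosome 4A was at 0 in all 5 infected libraries and held 3413 ± 933 in mock leaves, at least 4000-fold lower against a floor of 3 reads over the group, which covers counting error only. TraesCS2A03G0487300.1 on chromosome 2A held 339.9 ± 662 in infected and 7095 ± 3280 in mock leaves. It was at 0 in 3 of the 5 infected libraries, and without infected 7 d replicate 5, at 1516, its infected mean was 45.8. The mock mean of TraesCS5D03G0413700.1 was 0.576 without mock 7 d replicate 4. The log2 differences were 4.92 (SE 0.18), 4.82 (SE 0.167), -4.18 (SE 0.281) and -4.16 (SE 0.695), with adjusted p from limma of at most 4.24e-05. Each of these transcripts belongs to a gene with 2 transcripts in the table, and the sum of both moved less. Gene sums differed by 1.33 for TraesCS5D03G0413700, 1.28 for TraesCS5B03G0441800 and -1.18 for TraesCS2A03G0487300. For TraesCS4A03G0202400 the sum differed by -0.84 (limma adjusted p = 0.042), under the minimum of 1 unit. The small excess of higher transcripts turned on adjusted p alone (11264 higher, 13492 lower), on back-transformed values (6455 and 9480) and with upper-quartile scaling (1510 and 1568). Among genes with 1 transcript 1676 were called.

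At 14 d, 799 transcripts were higher and 2240 lower in infected than in mock leaves, again across kits. TraesCS5A03G0146100.1 and TraesCS5B03G0148400.1, on chromosomes 5A and 5B, were the lower transcripts with the largest differences under the naming rule. TraesCS5A03G0146100.1 held 344.3 ± 150 normalized counts in infected and 17460 ± 4690 in mock leaves (mean ± SD, n = 5), and TraesCS5B03G0148400.1 held 86.98 ± 33.2 and 8543 ± 3110. Their log2 differences were -4.68 (SE 0.171) and -4.45 (SE 0.186), with adjusted p from limma of 5.75e-15 and 5.01e-14. Among the higher transcripts, TraesCS1A03G0801400.1 on chromosome 1A held 8953 ± 4710 in infected leaves and was at 0 in all 5 mock libraries, at least 16700-fold higher against a floor of 3 reads over the group. TraesCS4A03G0697400.2 on chromosome 4A held 4752 ± 859 and 0.938 ± 2.1, the latter from mock 14 d replicate 4, the other mock libraries of 14 d being at 0. The log2 differences of these 2 transcripts were 5.38 (SE 0.408, limma adjusted p = 1.05e-09) and 4.60 (SE 0.116, limma adjusted p = 4.82e-18).

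The sums of both transcripts of the 2 genes with higher transcripts did not pass the same test. TraesCS1A03G0801400 totalled 15200 ± 5230 normalized counts in infected and 16660 ± 5360 in mock leaves at 14 d (mean ± SD, n = 5; limma adjusted p = 0.75). TraesCS4A03G0697400 totalled 6669 ± 765 and 5620 ± 1030 (limma adjusted p = 0.128). With transcripts summed per gene, 317 genes were higher and 1766 lower at 14 d, and 1131 higher and 1022 lower at 7 d, of 48577 genes tested. Of these, 134 genes were higher on both days, where independent lists would share 7.38, and 303 were lower on both days, against 37.2. The expected numbers take all tested genes as equally likely to be called and may be too low. The days share no library but do share the difference in kits. On adjusted p alone 9913 transcripts were higher and 14252 lower at 14 d, on back-transformed values 4666 and 10478, and 1773 were called among genes with 1 transcript.

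Genes whose transcripts were called in opposite directions were counted among the 6671 genes with more than 1 transcript tested. There were 130 such genes (1.95%) between infected and mock leaves at 7 d and 153 (2.29%) at 14 d. There were 29 between infected leaves at 14 and 7 d (49 without the 4 infected libraries of lowest depth, which leaves 2 libraries at 7 d) and 1 between mock leaves at 14 and 7 d. The comparisons of mock leaves at 7 and 14 d with 0 d gave 0 by limma, also at an unadjusted p under 0.05, with 473 and 561 such genes holding a call. With no minimum difference the numbers were 722 and 808 between infected and mock leaves at 7 and 14 d, 176 within infected leaves, and 20, 26 and 8 for mock 7 d against 0 d, 14 d against 0 d and 14 d against 7 d.

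**Figure D4:**
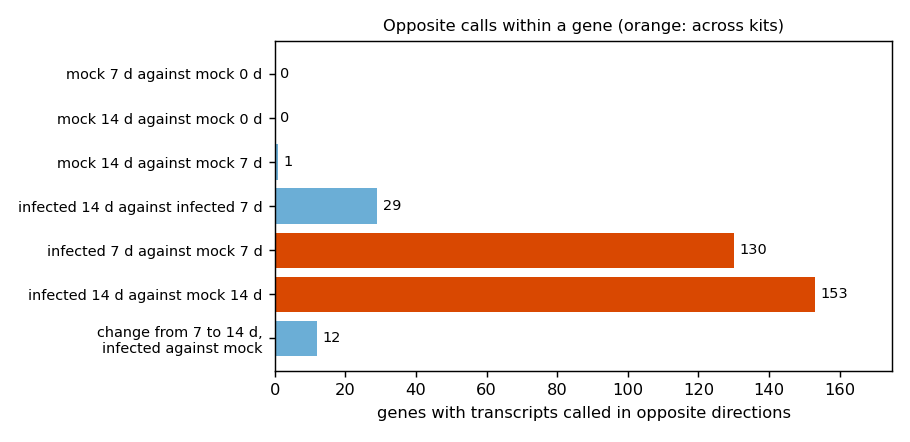
Number of genes with transcripts called in opposite directions in each comparison, out of 6671 genes with more than 1 transcript tested; orange bars are comparisons across kits and blue bars are within a kit or between changes within a kit. The counts across kits were 130 and 153 and those within a kit 0 to 29.

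The change from 7 to 14 d was compared between infected and mock leaves as a difference of differences. An effect of the kits drops out where it is the same number of deposited units at both days. A constant fold does not fully drop out for low transcripts, whose differences the deposited scale compresses, but does nearly so on back-transformed values. On these, 3251 of the 3441 calls were also made, among 11920 calls. Differences are mostly larger on that scale, so the overlap is high by construction and says little about the kits. The infected change was higher for 859 transcripts and lower for 2582. TraesCS1B03G1132200.1 on chromosome 1B rose in infected leaves from 320.6 ± 83.3 to 6084 ± 3070 normalized counts, with 11990 ± 5940 and 6142 ± 5000 in mock leaves (mean ± SD, n = 5). TraesCS5B03G1001000.1 on chromosome 5B went from 244 ± 103 to 1743 ± 1100 in infected and from 4505 ± 1290 to 782.1 ± 815 in mock leaves (442.6 at 14 d without replicate 5). TraesCS5A03G0146100.1 on chromosome 5A went from 924.5 ± 98.4 to 344.3 ± 150 in infected and from 334.1 ± 140 to 17460 ± 4690 in mock leaves. TraesCS2A03G0395300.1 on chromosome 2A went from 4306 ± 1370 to 703.6 ± 150 in infected and from 840 ± 171 to 9760 ± 2640 in mock leaves. The differences of log2 changes were 4.29 (SE 0.592), 4.04 (SE 0.535), -5.64 (SE 0.242) and -5.14 (SE 0.363), with adjusted p from limma of at most 1.02e-05.

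Of the 2582 transcripts with a lower infected change, 877 rose in mock leaves, 674 fell in infected leaves and 1124 were called in neither treatment alone. Of the 859 with a higher infected change, 288 rose in infected leaves, 112 fell in mock leaves and 483 were called in neither. The 877 were 78.7% of all transcripts that rose in mock leaves from 7 to 14 d, and the 112 were 70% of those that fell, shares that are raised by the mock libraries common to both tests. The infected change was higher for 25% of the calls, against 36.2% after quantile normalization and 35.1% after upper-quartile scaling. The split was closer to even on back-transformed values, at 42.8% (5105 higher, 6815 lower), and on adjusted p alone, at 46% (7508 and 8820).

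**Figure D5:**
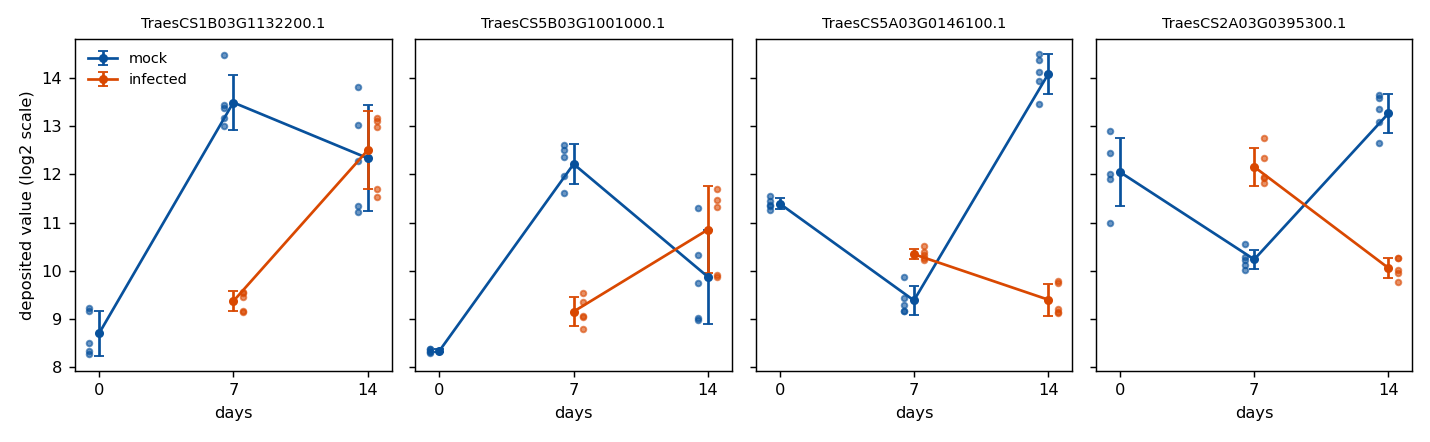
Deposited values (log2 scale) of the 4 transcripts named for the difference of changes against days, with group mean and SD (n = 5) and 1 small point per library, shifted sideways by treatment. TraesCS5A03G0146100.1 rose in mock leaves from 7 to 14 d and lay at 344.3 normalized counts in infected leaves at 14 d.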

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

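The tests of the kits and the position on the mock time course for the first pattern, of mock 14 d replicate 2 for the second, and of the shares without the shallowest libraries and per called gene for the third, were chosen after their results had been seen.

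The median of the transcripts that rose in mock leaves from 0 to 7 d rose in infected leaves from 7 to 14 d, and that of the transcripts that fell was lower, with 266 of 1540 and 280 of 1926 called the same way. Lower depth of some infected libraries was argued against, as far as the estimated depth ranks them. The rising set changed by 0.578 with the 6 deeper infected libraries and by 0.468 with all 10. Of the 6, 2 are of 7 d and 4 of 14 d. Kits were not tested separately: by the labels they do not differ between the infected days, and the exact permutation p of 0.00794 there is the pattern itself. A candidate explanation is that infected leaves stood at an earlier point of the course that mock leaves follow: all 5 infected libraries of 14 d correlated more closely with the mock mean of 7 d (0.855 to 0.889) than with that of 14 d (0.834 to 0.86). It stays open, since all 5 infected libraries of 7 d did so too, 3 of them being closest to mock 0 d and 2 to mock 7 d, and kits and infection differ together in these correlations.

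The median of the 1115 transcripts that rose in mock leaves from 7 to 14 d did not rise in infected leaves, although 39 of them were called as rising there, and the test of the difference between the changes called 3441 transcripts. A single library as the source of the 3441 calls was argued against. Leaving out each library in turn gave 3134 to 3690 calls, the fewest without mock 14 d replicate 2. This does not bear on the infected median, which the mock libraries enter only through the choice of the set. Compression of low values was argued against too: the 728 members with at least 100 normalized counts in both infected groups changed by a median of 1.42 in mock and -0.245 in infected leaves. After quantile normalization the whole set changed by 1.25 in mock and -0.101 in infected leaves, against scaling by a few abundant transcripts. The pattern may therefore be an effect of infection, as a hypothesis found and tested on the same data, and a kit effect that itself differs between days stays untested.

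Transcripts of the same gene were called in opposite directions in 130 genes at 7 d and 153 genes at 14 d between infected and mock leaves. Library chemistry as a source was given a bound of 3 in advance: the lowest share of such genes across kits was 4.48 times the highest share within a kit with all libraries, but 2.67 times without the 4 shallowest infected ones, where infected 14 d against 7 d rose from 29 to 49 genes with 2 libraries left at 7 d, and 1.72 times with all libraries as a share of genes with a call. The 4 shallowest infected libraries, as ranked by estimated depth, were argued against as the source across kits. Without them the number there was 1.01 times that with all libraries on the day with the smaller ratio. The infected libraries left, at 19.9 to 25.1 M reads, were still mostly below the mock ones, at 24.3 to 35.2 M. The gap in depth between treatments was therefore not tested. Infection changes together with the kits, so library chemistry, that gap and a change in transcript choice in infected leaves cannot be told apart.

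Chance as a source of the calls was tested by refitting 100 splits of the same samples in each comparison, the real one included. In each of the 7 comparisons 1 split, the real one, gave as many calls, the fewest that 100 splits allow. For the comparisons between groups this argues against a chance division of the samples. It does not speak to an effect shared by all libraries of a group. For the difference of changes the days were shuffled within each treatment. That removes every day effect, so this test cannot tell whether the changes differ between treatments. The real and the highest other counts were 3466 and 1416 for mock 7 d against 0 d, 4170 and 2031 for mock 14 d against 0 d, 1275 and 525 for mock 14 d against 7 d, and 1404 and 435 for infected 14 d against 7 d. They were 3021 and 494 for infected against mock at 7 d, 3039 and 1030 at 14 d, and 3441 and 1297 for the difference of changes.

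A sample far from the rest of its group was found in 9 of 82 checks, each of 1 measure, set or transcript in 1 group. Chance gives about 1 in 20 for independent normal values. These checks reuse the same libraries and include values at the floor, so their number cannot be set against that rate. The number after each is its gap to the nearest library over the range of the group. Infected 14 d replicate 3 had 13.3 M estimated reads against 22.4 to 25.1 M (0.771). Mock 0 d replicate 5 stood apart for the set that rose from 0 to 7 d, at 9.44 against 8.95 to 9.07 (0.763), and for TraesCS3A03G0131600.1 (0.895) and TraesCS3D03G0118800.1 (0.749). Mock 7 d replicate 2 stood apart for TraesCS4D03G0245600.1 (0.754) and TraesCS7D03G0117000.1 (0.828). Mock 7 d replicate 1 was at 11.05 for the set that fell from 7 to 14 d, against 10.74 to 10.8 (0.817). Mock 14 d replicate 2 was at 15.54 for TraesCS3A03G0131600.1, against 15.2 to 15.27 (0.809). Mock 14 d replicate 4 had the single value above 0 for TraesCS4A03G0697400.2 in its group (1), a gap fixed by the equal values of the others.

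The change from 7 to 14 d differed between infected and mock leaves, by the limma test of the difference, by 4.29 for TraesCS1B03G1132200.1, 4.04 for TraesCS5B03G1001000.1, -5.64 for TraesCS5A03G0146100.1 and -5.14 for TraesCS2A03G0395300.1.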

How the results depend on the processing

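Tests added after seeing the data are summing per gene, genes with 1 transcript and the removal of the 4 shallowest infected libraries. The deposited scale of the main counts was also chosen then. Back-transformed values with a pseudocount of 1 are nearest to the scale fixed in advance, though the back-transformation itself was decided after seeing the data. Of 192 alternative counts of calls, 154 stayed within 1.5 times the main count and 38 did not. Counts below are in the order mock 7 d against 0 d, mock 14 d against 0 d, mock 14 d against 7 d, infected 14 d against 7 d, infected against mock at 7 d and at 14 d, and the difference of changes. The main counts were 3466, 4170, 1275, 1404, 3021, 3039 and 3441. Back-transformed values gave 12518, 14767, 5362, 9520, 15935, 15144 and 11920 with a pseudocount of 1. With a pseudocount of 0.5 they gave 12205, 14365, 5177, 9477, 15754, 15013 and 11700, and with one of 5, 12861, 15275, 5708, 9113, 15659, 14765 and 12260. The deposited scale compresses differences of low transcripts, so fewer reach 1 unit. With no minimum difference 21676, 25391, 10710, 16162, 24756, 24165 and 16328 passed, and with a minimum of 2 units 582, 849, 176, 105, 326, 367 and 555. With only the groups compared in the fit, 28332, 30160, 15965, 10017, 24116, 20095 and 15002 passed with no minimum difference. Of these, 3431, 4157, 1209, 1207, 2942, 2886 and 3369 also reached 1 unit. Testing genes with 1 transcript alone gave 899, 1676 and 1773 for infected 14 d against 7 d and for infected against mock at 7 and 14 d, with 37121 transcripts tested instead of 57301. Without the 4 shallowest infected libraries, which leaves 2 of infected 7 d, the last 4 comparisons gave 1653, 3189, 3096 and 3564.

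Leaving out each replicate in turn gave 3248 to 3743, 3813 to 4502, 1074 to 1408, 1412 to 1527, 2907 to 3122, 2718 to 3213 and 3134 to 3690 calls in the same order. Named transcripts were picked for the largest differences, so their stability says little about other calls. Of 761 alternative values of named transcripts, 758 kept their direction and their side of the threshold. The others came from summing per gene, which adds the partner transcript by construction: TraesCS1A03G0801400.1 at 14 d turned to -0.127 (limma adjusted p = 0.75, against 3.05e-14 to 0.75 over its alternatives). TraesCS4A03G0202400.2 at 7 d and TraesCS4A03G0697400.2 at 14 d fell short of the threshold at -0.84 and 0.24.

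Replicate numbers did not pair the samples. With the number in the titles as a replicate block, 3466, 4170, 1270, 1389, 3013, 3036 and 3432 transcripts were called, and the block changed no call of a named transcript. Deviations of same-numbered libraries from their group means correlated at -0.291 to 0.469, and 4 of 25 libraries correlated best with their own number (5 of 25 for the number in the descriptions). Not run were rescaling to host genes, count models, gene list tests and the share of pathogen reads. In infected libraries, of lower estimated depth, 24080 to 31044 transcripts stood at a count of 0, against 14206 to 16134 in mock libraries, so their absence was not shown.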

Other observations

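All values in this part were computed after the data had been seen. Called genes were spread over all 3 wheat subgenomes, named by the letter in the identifier. With transcripts summed per gene, the infected change from 7 to 14 d was lower than the mock change for 4.75% of tested genes of subgenome A, 4.87% of B and 5.37% of D. Genes that rose in mock leaves from 7 to 14 d were 2.11%, 2.16% and 2.44%. By Fisher's exact test of each chromosome against the rest, 0 of 308 tests of called genes, over 7 comparisons and both directions, passed a Benjamini-Hochberg adjusted p of 0.05. The smallest adjusted p was 0.0893, and 42 had an unadjusted p under 0.05.

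Genes called in the same direction were neighbours more often than a shuffle of calls within each chromosome gave. Neighbours are tested genes with consecutive positions in the order of their identifiers. Among genes that rose in mock leaves from 7 to 14 d there were 104 neighbouring pairs, against a mean of 24.8 and a highest value of 41 over 1000 shuffles. Among genes that fell in infected leaves from 7 to 14 d there were 49, against a mean of 11.4 and a highest value of 24. In the 14 lists of called genes the ratio to the shuffled mean was 2.14 to 16.4, and 13 lists exceeded every shuffle. The exception was the list of genes higher in infected than in mock leaves at 14 d, with 5 pairs against a highest shuffled value of 9. The longest run held 7 genes on chromosome 2A, all lower in mock leaves at 7 d than at 0 d. Duplicated neighbouring genes that share reads were not examined.

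Some transcripts were seen in one treatment alone. At a count of 0 in all 10 infected libraries were 6690 transcripts, of which 874 had a mean of at least 10 normalized counts in mock libraries. At 0 in all 15 mock libraries were 880, of which 449 had a mean of at least 10 normalized counts in infected libraries. These lists mix infection, kit and depth, and fungal reads assigned to wheat transcripts were not examined. TraesCS1A03G0801400.1 was at 0 in all 15 mock libraries and held 2447 ± 2370 normalized counts in infected leaves at 7 d (mean ± SD, n = 5), with a mean of 1505 without infected 7 d replicate 5.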
